A study of Mus musculus with 3 samples.

How the data were processed

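RNA of mouse ES cells and of MEF was compared on 3 two-colour Agilent whole mouse genome arrays. Per the labels, each array carried RNA of 1 ES cell replicate in Cy3 (green) and MEF RNA in Cy5 (red), with no dye swap; replicates were named by the labels' own numbers. All 3 arrays lay on 1 slide and were scanned together, per the file headers, so neither slide nor scan could be tested as a batch. A line of the design text calls the Cy5 sample by another name than MEF; the sample labels were followed.

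Per the file headers, the authors read the images with Agilent Feature Extraction 9.5.3.1, and the probe coordinates in the files use mouse build mm7. The deposited spot and background intensities are mean and median pixel brightness, without background subtraction. Deposited processed intensities are background-subtracted and dye-normalized by that software (linear and LOWESS), with substitutes for low signals, per the file headers. The deposited log10 ratio is red over green of the processed signals, thus MEF over ES cells, and is exactly 0 for 11.9% to 14.2% of gene spots per array. The authors also deposited a log2 value table for the series. Set against the scanner values of the same array, it came within 0.01 of the sign-turned log ratio for 85.4% to 87.8% of probes (r = 0.998, 1.00 and 0.999 across probes), so it holds log2 ES cells over MEF of processed signals. Its columns have medians of 0.213, 0.0859 and -0.143 and are thus not centred; what was done to the remaining probes stays unknown.

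Mean signals and median local backgrounds were corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3, and log ratios were normalized within each array by loess, with control spots given weight 0. Ratios were turned to ES cells over MEF. Spots flagged as outliers (117 to 144 gene spots per array) were left out, and spots of a probe were averaged. The offset shrinks ratios of dim genes. Median gene spot signals were 398 to 421 in the ES cell channel and 381 to 391 in the MEF channel, over median backgrounds of 45 to 56 and 38 to 41.5. Saturation affected 2 gene spots in the MEF channel of replicate 1. The number of arrays limits the precision.

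Names came from the accession of the probe, without version, through the RefSeq gene table of assembly GRCm38.p6 for 22951 probes, and from its symbol, synonym or gene number for 10062; 8161 probes kept the name in the file. No coordinate of that assembly was used. A probe was kept if well above background in the ES cell channel or in the MEF channel on all 3 arrays (29502 of 41174 probes), and the probe with the highest mean brightness stood for its gene. Of 6879 genes with more than 1 tested probe, 69 had called probes of opposite sign, among them Cdk6, Fgfr3 and Fgfr4.

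The mean log2 ratio of each gene was tested against 0 with limma (intercept only, lmFit and eBayes, Benjamini-Hochberg over 19488 genes), and a gene was called at an adjusted p under 0.05 and a log2 ratio of at least 1 in size. Without the fold minimum, 95.5% of genes had an adjusted p under 0.05, so the fold minimum sets the calls. Lists were tested with camera (preset correlation 0.01, and again with an estimated one, Benjamini-Hochberg over 37 lists), and so were chromosomes. The 37 lists, the groups, the tests and most alternatives were fixed before the data were examined. Of the 851 list entries, those without a matched probe were Fgf4 (in 2 lists), L1td1, Prdm14, Tuba3b, Rtl1, Hoxc11, Psme2, Nlrc5, Lif and Amt. Genes named in the text followed a rule also fixed then: the 8 highest and 8 lowest ratios among called genes above background, unsaturated and of one sign on all arrays; the 4 brightest genes of each cell type without signal in the other; the 2 highest and 2 lowest called members of each list; and Pou5f1, Nanog, Sox2, Klf4, Myc, Col1a1, Thy1, Cdh1, Cdh2, Vim, Actb and Gapdh. Cdk6, Fgfr3, Fgfr4, Ddx3y, Uty, Aqp4 and members of the added cell type lists were named after their values were seen. Some genes that the rule or these lists take in are not reported here.

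The procedure was tested on simulated arrays built from the real brightness and backgrounds, with 29502 probes run and 200 of them changed. For the comparison of ES cells with MEF, all 50 probes of each true log2 ratio (-3, -1.5, 1.5 and 3) were called with the right sign. Of 29302 unchanged probes 0 were called. The median estimates were -2.90, -1.42, 1.42 and 2.87. The simulated changes were few and balanced, and no dye bias of single probes was simulated. In the data 42.8% of tested genes were called, so the simulation cannot show how such wide change or such bias affects the calls.

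Alternatives were the scanner software's processed signals, no background subtraction, normexp with offset 0, median centring, Aquantile after loess, no filter on dim probes, a filter on both channels, the mean of all probes, every probe on its own, outlier spots kept, saturated genes left out, limma's treat, no fold minimum, the authors' value table, leaving out each array, array weights and an estimated correlation in camera. Removal of a trend on probe GC content was added after the data were seen, since the median log2 ratio ran from 0.31 at a GC content up to 30% to -0.48 above 60%.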

Results

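Gene expression was measured in mouse embryonic stem (ES) cells, pluripotent cells derived from the early embryo, and set against mouse embryonic fibroblasts (MEF), the mesenchymal cells commonly grown from dissociated fetuses. The stated question was how expression in the ES cells differs from that in MEF. The ES cells were kept in medium with fetal serum and leukemia inhibitory factor, a cytokine that maintains self-renewal, and the MEF in a plainer serum medium. RNA of 3 ES cell replicates, labelled with Cy3, was hybridised to 3 two-colour whole-genome oligonucleotide arrays, each together with MEF RNA labelled with Cy5. Every array held 41174 probes for genes. Between 68.6% and 70.6% of the gene spots were well above background in the ES cell channel and between 68.2% and 74.0% in the MEF channel. The test covered 19488 genes, of which 16949 were well above background in both channels on all 3 arrays. All ratios are ES cells over MEF, so a negative log2 value is a lower level in ES cells.

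The 3 arrays gave nearly the same ratios. Across 19463 genes, which are not independent replicates, the correlation of log2 ratios between arrays was 0.998 for each pair. The median SD of a gene's log2 ratio was 0.028. Among 245 probes spotted 10 times on each array, the median SD between array means was 0.018, against 0.019 expected from the spread of spots within an array alone, and 14.3% of these probes differed between arrays at a permutation p under 0.05, where chance gives 5%. The median SD between arrays was 0.032 in the ES cell channel and 0.031 in the MEF channel. Nothing in the labels says that the ES cell replicates came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. MEF RNA counts as 1 control, and its own spread is left out of every test. No dyes were swapped, so a bias of either dye for single probes stays in every ratio.

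ES cells and MEF differed widely, with pluripotency and germ cell genes at one end of the ratios and collagens and other matrix genes at the other. In ES cells 3971 genes were called higher and 4374 lower, at an adjusted p under 0.05 (limma) and a change of at least 2-fold. Of these, 1313 were higher and 1872 lower by at least 4-fold, and 34 were higher and 72 lower by at least 32-fold. By the brightest probe of each gene, the highest ratio belonged to Mycn, a Myc family transcription factor, at 7.18 ± 0.040 (log2, SD, n = 3 arrays), a 145-fold difference with an adjusted p of 1.63e-07. Next came Mageb16 at 6.61 ± 0.093, Zfp42 (Rex1, a classic ES cell marker) at 6.33 ± 0.051, the meiotic gene Hormad1 at 6.08 ± 0.16, the testis cytochrome c gene Cyct at 6.04 ± 0.15, the piRNA pathway gene Mael at 5.93 ± 0.068, the nuclear receptor gene Nr0b1 (Dax1) at 5.90 ± 0.019 and Sult6b1 at 5.89 ± 0.059. The lowest ratio belonged to Igfbp5, which encodes a secreted binding protein of insulin-like growth factors, at -8.32 ± 0.036, a 319-fold difference with an adjusted p of 1.63e-07. The fibrillar collagen genes Col1a1 (-8.10 ± 0.016), Col3a1 (-7.59 ± 0.0076) and Col1a2 (-7.36 ± 0.060) followed, then the matrix gene Postn (-7.08 ± 0.049), Col14a1 (-6.87 ± 0.11), the growth factor gene Ptn (-6.86 ± 0.026) and Ogn (-6.78 ± 0.019), which encodes a small proteoglycan. These 16 genes were above background in both channels and kept their sign on every array. Averaging all probes gave smaller ratios of 5.25 for Mycn, -5.85 for Igfbp5, -5.93 for Col1a1, -3.99 for Col3a1, -5.19 for Col1a2, -5.30 for Postn and 5.51 for Mageb16, and a larger one of 6.61 for Zfp42. Over all probes Mycn thus lay below every other of the 8 highest genes, and Zfp42 lay above them all. Col14a1 (-6.87), Ptn (-6.86), Ogn (-6.78) and Col1a1 (-5.93) lay below Igfbp5. Processed signals of the scanner software gave 7.35 for Mageb16, 7.23 for Hormad1, 7.03 for Cyct, 6.98 for Sult6b1 and -5.34 for Col1a1, so the order depends on the choice of probe and of signal. On the coordinates in the scanner files, which use mouse build mm7, the Mycn probe lay on chromosome 12 from 12999078 to 12999137, the Igfbp5 probe on chromosome 1 from 73100116 to 73100175 and the Col1a1 probe on chromosome 11 from 95060800 to 95060859. No gene annotation of that build was used, so whether these stretches are coding or untranslated was not determined.

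**Figure D1:**
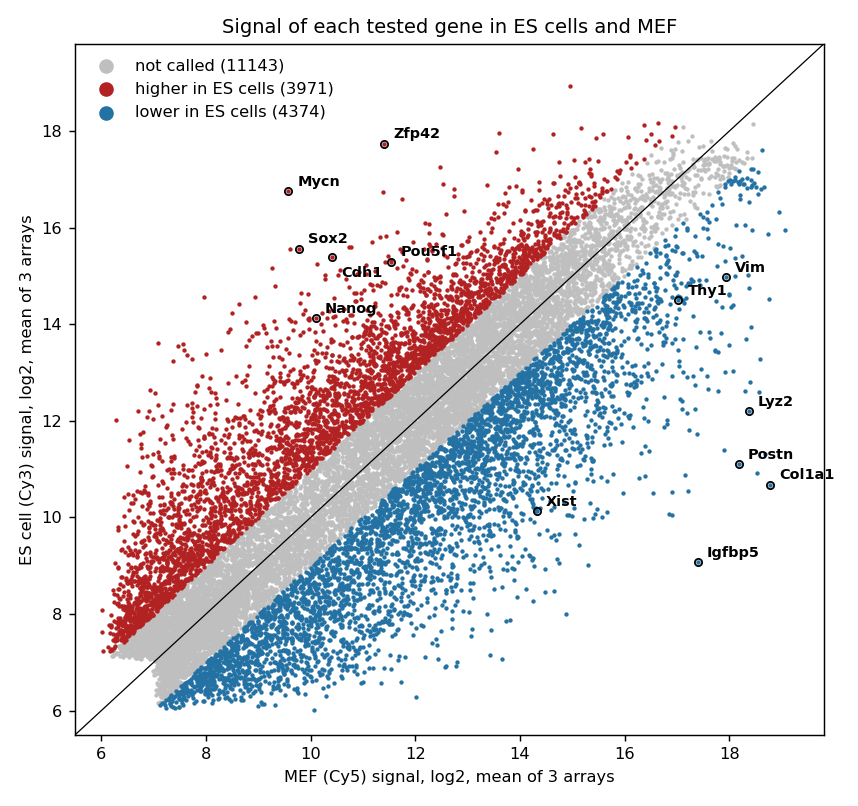
Signal of the 19488 tested genes in MEF (horizontal axis, Cy5) and ES cells (vertical axis, Cy3), as log2 means of 3 arrays after normalization; red points are the 3971 genes called higher and blue points the 4374 called lower in ES cells, and the diagonal marks equal signal. Mycn, Zfp42 and Sox2 lie far above the diagonal, while Igfbp5, Col1a1 and Postn lie far below it.

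Some genes had signal in one cell type only, and for these a ratio is a lower bound. No probe of 623 tested genes was well above background in MEF on any array, and 372 of these were called higher in ES cells; 710 genes had no such probe in ES cells, and 392 of them were called lower. Bounds set the mean signal of the bright channel against, per array, the higher of the dim probe's own signal and the lowest signal of any probe well above background, and they are open to dye bias. The brightest genes of the first kind were Lrrc34, at least 42.7-fold higher in ES cells (adjusted p = 5.36e-07, limma), Dnajc6, which encodes an auxilin of clathrin uncoating (at least 37.9-fold), Ildr1, a gene of tricellular junctions (at least 30.6-fold), and the meiotic gene Meioc (at least 30.4-fold). In the other direction, Gfap, the intermediate filament gene of astrocytes, was at least 37.8-fold lower in ES cells by its brightest probe (adjusted p = 1.63e-07, limma). The basement membrane gene Hmcn1 was at least 22.9-fold lower, Lcp2, a signalling adaptor of blood cells, at least 19.5-fold, and the coagulation factor gene F13a1 at least 17.7-fold. Over all their probes Ildr1, Gfap and Hmcn1 had smaller ratios than by the brightest probe, and with processed signals the ratios of all 8 genes were larger.

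Genes of naive pluripotency were higher in ES cells throughout. All 37 measured members of that list were called higher, with a median log2 ratio of 3.75, while Fgf4, L1td1 and Prdm14 were not matched to a probe. Among the core factors, Sox2 stood at 5.79 ± 0.062, Nanog at 4.02 ± 0.028 and Pou5f1 (Oct4) at 3.75 ± 0.055 (log2, SD, n = 3 arrays). The Pou5f1 probe, on chromosome 17 from 33612047 to 33612107, and the Nanog probe, on chromosome 6 from 122750894 to 122750953, were above background in MEF as well. Klf4, which fibroblasts also express, differed least in the list, at 1.28 ± 0.014. Myc, the fourth of the factors used to reprogram fibroblasts, was lower in ES cells, at -1.54 ± 0.0057. Germline genes went the same way: 23 of 26 measured members were called higher and none lower, with a median of 3.98, led by Hormad1 and Mael. The preset set test (camera) called both lists, with adjusted p-values of 5.20e-10 and 2.86e-07. With an estimated correlation, a form of camera with little power on 3 arrays, neither list was called. The adjusted p was then 0.347 for pluripotency and 0.309 for germline genes.

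Epithelial genes were higher in ES cells. Of 28 epithelial junction and keratin genes, 25 were called higher and none lower, with a median of 2.46 and a camera adjusted p of 1.35e-06 (adjusted p = 0.309 with an estimated correlation). Cdh1 (E-cadherin) stood at 4.99 ± 0.048, while Cdh2 (N-cadherin) was lower at -2.87 ± 0.044. The epithelial transcription factor gene Grhl2 had the highest ratio of the list, 5.04 ± 0.15, though it was well above background in MEF on only 1 of 3 arrays the mean of its probes was 2.98, and processed signals gave 6.71. One-carbon, serine and threonine metabolism was a mixed list with 10 of 19 members called higher and 2 lower (median 2.30-fold higher, camera adjusted p = 0.0223; adjusted p = 0.280 with an estimated correlation). Gldc, of the glycine cleavage system, stood at 5.12 ± 0.045 and Tdh (threonine dehydrogenase), which mouse ES cells rely on, at 4.02 ± 0.029, whereas Phgdh, of serine synthesis, stood at -1.54 ± 0.022.

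Genes of proliferation were higher in ES cells. DNA replication had 38 of 41 members called higher and 1 lower (median 1.88), mitosis 28 of 30 higher and none lower (median 1.96), and DNA repair 24 of 30 higher and none lower (median 2.22). Camera gave adjusted p-values of 1.89e-09, 1.50e-08 and 4.58e-07 for these lists, and for each of them the adjusted p was 0.266 with an estimated correlation. The origin recognition gene Orc1 stood at 2.98 ± 0.023, the replication clamp loader gene Rfc5 at 2.74 ± 0.038, cyclin B1 (Ccnb1) at 3.38 ± 0.024, the spindle checkpoint kinase gene Bub1 at 3.21 ± 0.012, the mismatch repair gene Msh6 at 3.25 ± 0.074 and the exonuclease gene Exo1 at 3.15 ± 0.014. The primase subunit gene Prim2 was the member called lower, at -1.40 ± 0.0084, and averaging its probes ended that call (-0.25). Ribosome biogenesis had 23 of 25 members called higher and none lower (median 1.48, camera adjusted p = 3.31e-07; adjusted p = 0.266 with an estimated correlation), with Dkc1, of the pseudouridine synthase complex, at 3.21 ± 0.028 and Gar1 at 2.18 ± 0.018. G1 cyclins, CDK inhibitors and senescence genes were not called as a list (camera adjusted p = 0.255), with 10 of 20 members lower and 1 higher. Cyclin E1 (Ccne1) stood at 1.46 ± 0.024, cyclin D2 (Ccnd2) at -3.98 ± 0.013 and the CDK inhibitor gene Cdkn1c at -3.63 ± 0.010.

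Chromatin genes split. Polycomb and remodelling genes had 18 of 30 members called higher and 3 lower (median 1.11, camera adjusted p = 3.16e-04; adjusted p = 0.266 with an estimated correlation). Cbx7 at 4.09 ± 0.10 and Mtf2 at 3.41 ± 0.015, both polycomb components, were highest, and the remodelling subunit gene Smarcc2 at -1.68 ± 0.0074 and the polycomb gene Bmi1 at -1.44 ± 0.036 were lowest. DNA methylation and demethylation genes were not called as a list (camera adjusted p = 0.302), with 8 of 15 members higher and 4 lower. The de novo methyltransferase gene Dnmt3b (4.52 ± 0.080) and its cofactor gene Dnmt3l (4.07 ± 0.060) were highest, and Tet3 (-2.01 ± 0.045), which encodes a demethylation enzyme, was among those called lower, at -1.24 over all its probes.

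Markers of early lineages went both ways. Primed epiblast and primitive streak genes had 6 of 11 members higher and 1 lower (median 1.13, camera adjusted p = 0.0333; adjusted p = 0.309 with an estimated correlation). Otx2 stood at 4.45 ± 0.068 and Sp5 at 2.82 ± 0.15, the latter above background in MEF on 1 of 3 arrays and at 4.09 with processed signals, and Gsc at -1.83 ± 0.031. This list's call was lost with the scanner software's processed signals, with the authors' value table and among genes above background in both channels. Endoderm genes (4 of 13 higher, 3 lower, camera adjusted p = 0.910) and trophoblast genes (4 of 9 higher, 2 lower, camera adjusted p = 0.368) were not called as lists. The mean of the endoderm list was -0.19, while its median was 0.055 and its test pointed upward; its median ran from -0.25 to 0.17 under the alternative settings. Dab2 (-3.29 ± 0.023) and Pdgfra (-2.83 ± 0.018), both also expressed by fibroblasts, were lowest among the endoderm genes, with -1.78 for Pdgfra over all its probes, and Cubn stood at 1.38 ± 0.015. For Hnf4a the brightest probe gave at least 6.28-fold higher in ES cells, but another probe, used under 5 other settings, gave log2 ratios between -0.25 and -0.18. Tfap2c stood at 4.67 ± 0.067 and Esx1 at least 12.6-fold higher among the trophoblast genes, with Gata2 at -2.42 ± 0.066 and Gata3 at -2.38 ± 0.034. Neural and neural crest genes had 9 of 14 members lower and 1 higher (median -1.58, camera adjusted p = 0.0228; adjusted p = 0.351 with an estimated correlation). Ncam1, which encodes a neural cell adhesion molecule, stood at -3.22 ± 0.013, and -1.63 over all its probes. Pax6, the member called higher at 1.59 ± 0.38, lost its call when its probes were averaged (0.84). The neural list's call was lost among genes above background in both channels and with a trend on probe GC content removed.

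**Figure D2:**
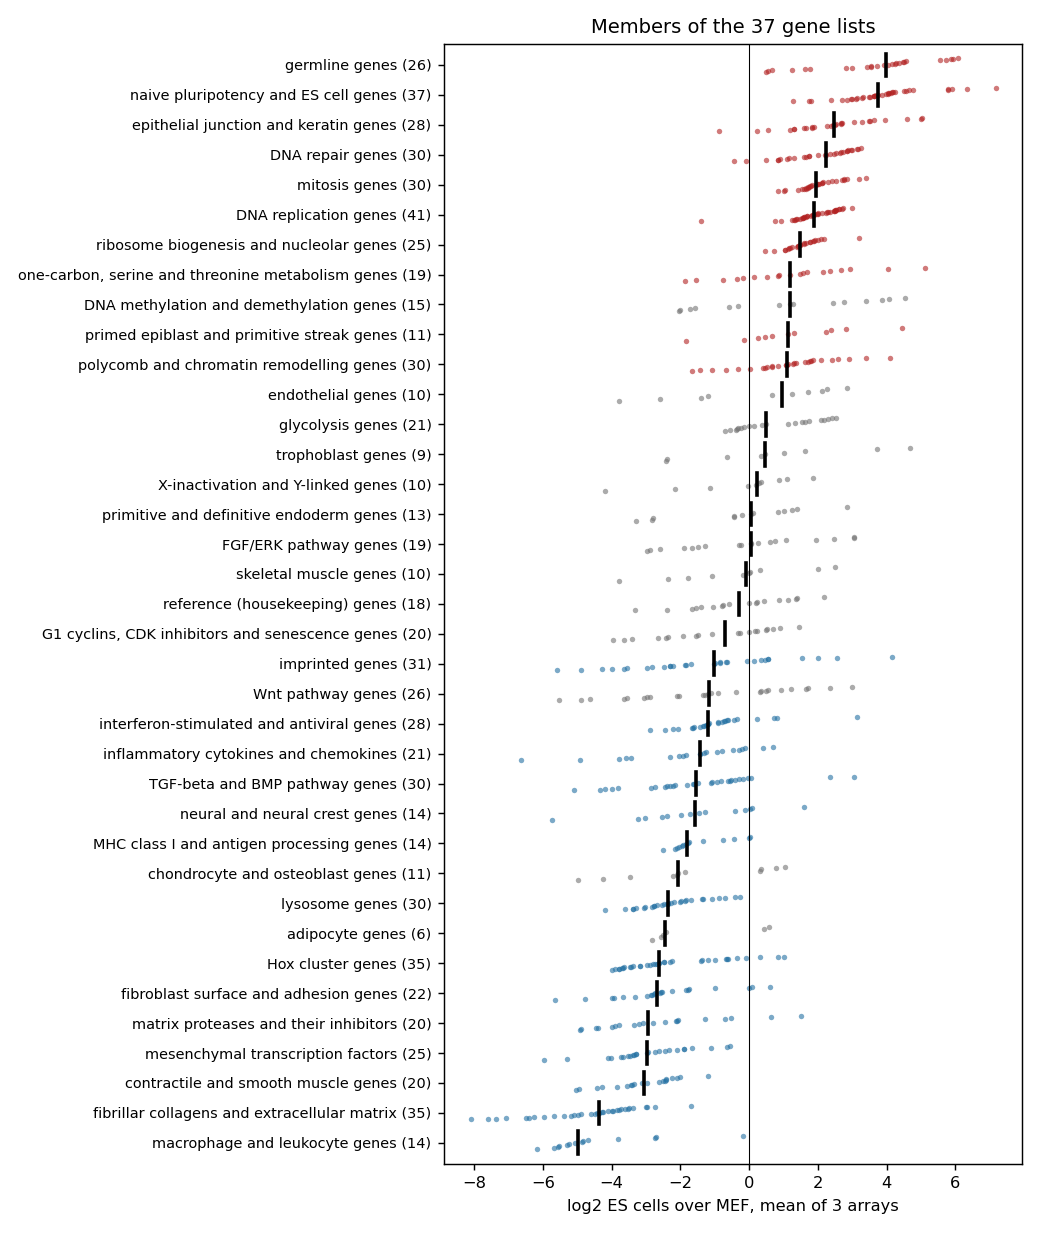
Log2 ratio of ES cells over MEF (mean of 3 arrays) of every measured member of the 37 gene lists, ordered by list median (black bar), with the number measured in parentheses; red lists were called higher and blue lists lower with the preset correlation, and grey lists were not called. Germline genes (median 3.98) and naive pluripotency genes (3.75) sit at the top, and matrix genes (-4.38) and macrophage genes (-4.97) at the bottom.

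Matrix and mesenchymal genes were lower in ES cells. All 35 collagen and extracellular matrix genes were called lower, with a median of -4.38, as were all 20 contractile genes (median -3.05), 23 of 25 mesenchymal transcription factors (median -2.97), 18 of 22 fibroblast surface genes (median -2.67) and 16 of 20 matrix proteases and inhibitors (median -2.94). Camera gave adjusted p-values of 1.40e-09, 1.83e-06, 1.36e-06, 9.95e-05 and 1.76e-04 for these lists, and with an estimated correlation the adjusted p was 0.266 for each. Meox1 (-5.97 ± 0.016) and Foxc1 (-5.30 ± 0.021) were lowest among the transcription factors, Tagln (-5.04 ± 0.056) and Myl9 (-4.95 ± 0.023) among the contractile genes, the collagen receptor gene Itga11 (-5.66 ± 0.021) and Pdgfrb (-4.78 ± 0.015) at the surface, and Adamts1 (-4.92 ± 0.024) and Serpinf1 (-4.90 ± 0.0054) among proteases and inhibitors. Vim (vimentin) stood at -2.96 ± 0.037 and the surface marker Thy1 at -2.52 ± 0.026, with -1.86 for Vim over all its probes. Mmp10 was the protease called higher, by 2.82-fold.

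Hox genes, which pattern the body axis, were lower in ES cells for 26 of 35 measured members, with a median of -2.64 (camera adjusted p = 1.12e-05; adjusted p = 0.315 with an estimated correlation). Hoxa10 (-4.00 ± 0.078) and Hoxc6 (-3.90 ± 0.024) were lowest, with -4.92 for Hoxa10 from processed signals. Hoxc13 was called higher by at least 1.76-fold, at the edge of the threshold, and its log2 ratio fell below it without replicate 2 (0.92), with median centring (0.994), with array weights (0.992) and with a trend on probe GC content removed (0.91), but rose to 3.03 with processed signals. TGF-beta and BMP pathway genes had 18 of 30 members lower and 2 higher (median -1.55, camera adjusted p = 6.31e-05; adjusted p = 0.309 with an estimated correlation). The ligand gene Tgfb3 stood at -5.10 ± 0.034 and its receptor gene Tgfbr2 at -4.35 ± 0.024, with -2.79 for Tgfbr2 over all its probes, while the activin receptor gene Acvr2b (3.06 ± 0.069) and the inhibitory Smad7 (2.35 ± 0.034) were higher.

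Genes of macrophages and other leukocytes had the lowest list median, -4.97, with 13 of 14 members lower in ES cells (camera adjusted p = 6.27e-05; adjusted p = 0.266 with an estimated correlation). The lysozyme gene Lyz2 stood at -6.18 ± 0.012 and the receptor gene Csf1r at -5.69 ± 0.075, and both were above background in ES cells on all 3 arrays. Averaging all probes gave -5.16 for Lyz2 and -3.59 for Csf1r. Lysosome genes had 26 of 30 members lower and none higher (median -2.36, camera adjusted p = 1.95e-07; adjusted p = 0.266 with an estimated correlation), with the cathepsin genes Ctss (-4.21 ± 0.012) and Ctsh (-3.62 ± 0.011) lowest. Interferon-stimulated genes had 15 of 28 lower and 1 higher (median -1.19), and MHC class I and antigen processing genes 10 of 14 lower and none higher (median -1.81). Inflammatory cytokine and chemokine genes had 13 of 21 lower and none higher (median -1.43). Camera gave these 3 lists adjusted p-values of 8.97e-04, 0.00173 and 3.71e-04, and adjusted p = 0.266, 0.266 and 0.309 with an estimated correlation. Isg15 (-2.89 ± 0.033), Ifih1 (-2.45 ± 0.013), B2m (-2.51 ± 0.043), Tap2 (-2.17 ± 0.048), Cxcl12 (-6.65 ± 0.033) and Tnf (-4.91 ± 0.051) were the lowest of their lists, with -5.92 for Cxcl12 over all its probes and -5.63 for Tnf from processed signals, and Oas2 was the interferon-stimulated gene called higher, at 3.15 ± 0.036.

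FGF/ERK genes (5 of 19 higher, 7 lower, camera adjusted p = 0.970) included the feedback and target genes Spry4 (3.05 ± 0.026) and Etv5 (3.05 ± 0.031) at one end, with 1.99 for Spry4 and 2.40 for Etv5 over all their probes, and Egr1 (-2.97 ± 0.020) and Spry1 (-2.90 ± 0.020) at the other; the median of this list was 0.049, or -0.029 with a trend on probe GC content removed, and its mean was -0.11. Wnt genes (5 of 26 higher, 14 lower, camera adjusted p = 0.300) ran from Tcf7 (2.98 ± 0.021) and Lef1 (2.35 ± 0.020) to Fzd1 (-5.52 ± 0.025) and Ccn4 (-4.88 ± 0.018), with 2.24 for Tcf7 and 1.66 for Lef1 over all their probes. Glycolysis genes had 10 of 21 higher and none lower (median 0.49, camera adjusted p = 0.115), with Pdk1 at 2.53 ± 0.045 and the glucose transporter gene Slc2a1 at 2.41 ± 0.044. Adipocyte genes had 4 of 6 lower (camera adjusted p = 0.330), with Cebpa at -2.83 ± 0.11, or -1.84 over all its probes, and Pparg at -2.56 ± 0.028. Chondrocyte and osteoblast genes had 7 of 11 lower and 1 higher (camera adjusted p = 0.293), with Col2a1 at -4.98 ± 0.017 and Spp1 at -4.24 ± 0.038; Matn1, the member called higher by at least 1.93-fold, fell below the threshold without replicate 2 (log2 ratio 0.998) but stood at 2.96 with processed signals. Skeletal muscle genes had 4 of 10 lower and 2 higher (camera adjusted p = 0.651), from Myh3 at 2.50 ± 0.045 and Tnnt1 at 2.00 ± 0.031 to Acta1 at -3.80 ± 0.020 and Tnnt3 at -2.36 ± 0.070, or -3.22 with processed signals. Endothelial genes had 5 of 10 higher and 4 lower (camera adjusted p = 0.546), with Robo4 at 2.86 ± 0.083 and Cldn5 at 2.26 ± 0.13, Erg at least 13.5-fold lower, and Emcn at -2.58 ± 0.28 and above background in ES cells on 1 of 3 arrays. Processed signals gave 2.98 for Cldn5 and -4.28 for Emcn.

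Genes often used as references were not level. Of 18 such genes 4 were called higher and 6 lower, with a median of -0.29 (camera adjusted p = 0.884). Actb stood at -1.56 ± 0.0095 and Gapdh at 2.17 ± 0.017, Tbp at 1.38 ± 0.020 and Gusb at -2.40 ± 0.0047 (log2, SD, n = 3 arrays). The scanner files place the Actb probe on the X chromosome, so its signal may include a copy of that gene. The other Actb probe stood at -1.42. Gapdh rests on 1 probe, designed on a cDNA clone. Its log2 signal was 11.10 in ES cells and 8.93 in MEF, below the 12.57 and 14.13 of Actb. So dim a probe may not follow the Gapdh transcript, and its ratio is weak evidence on that gene.

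Imprinted genes, expressed from 1 parental allele, were lower in ES cells for 16 of 31 measured members and higher for 4 (median -1.01, camera adjusted p = 0.0279; adjusted p = 0.475 with an estimated correlation). Igf2 (-5.59 ± 0.056) and Plagl1 (-4.88 ± 0.053) were lowest, and Phlda2 (4.16 ± 0.021) and Ddc (2.56 ± 0.027) highest. Averaging all probes gave -4.04 for Plagl1 and 1.63 for Ddc. X-inactivation and Y-linked genes were not called as a list (camera adjusted p = 0.546), and their median (0.23) and mean (-0.29) differed in sign. Xist, the RNA that coats the inactive X chromosome, stood at -4.18 ± 0.011, with its 4 probes between -4.18 and -0.93, and -3.04 over all of them, and its antisense partner Tsix at 1.86 ± 0.044. Of the Y-linked genes, Kdm5d stood at -2.16 ± 0.035, Ddx3y at -1.13, Uty at 0.27 and Eif2s3y at 1.09 ± 0.021. The calls of Ddx3y and Eif2s3y did not hold under every setting: Ddx3y was at -0.87 with median centring and -0.63 over its probes, and Eif2s3y at 0.99 with a trend on probe GC content removed.

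Over all 37 lists, 10 were called higher and 14 lower with the preset correlation and none with an estimated one, where 4 lists had an unadjusted p under 0.05 and the lowest adjusted p was 0.266. In each of the 37 lists the counts of called members adjusted over the list alone were equal to those over all genes tested. No chromosome stood apart as a whole. Camera called 0 of the 20 chromosomes tested (1 to 19 and X), 0 at an unadjusted p under 0.05, with either correlation. The medians ran from -0.15 for chromosome 6, over 1015 genes, to 0.11 for chromosome 8, over 983 genes (adjusted p = 0.939 for both), and the X chromosome had a median of 0.0056 over 709 genes.

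**Figure D3:**
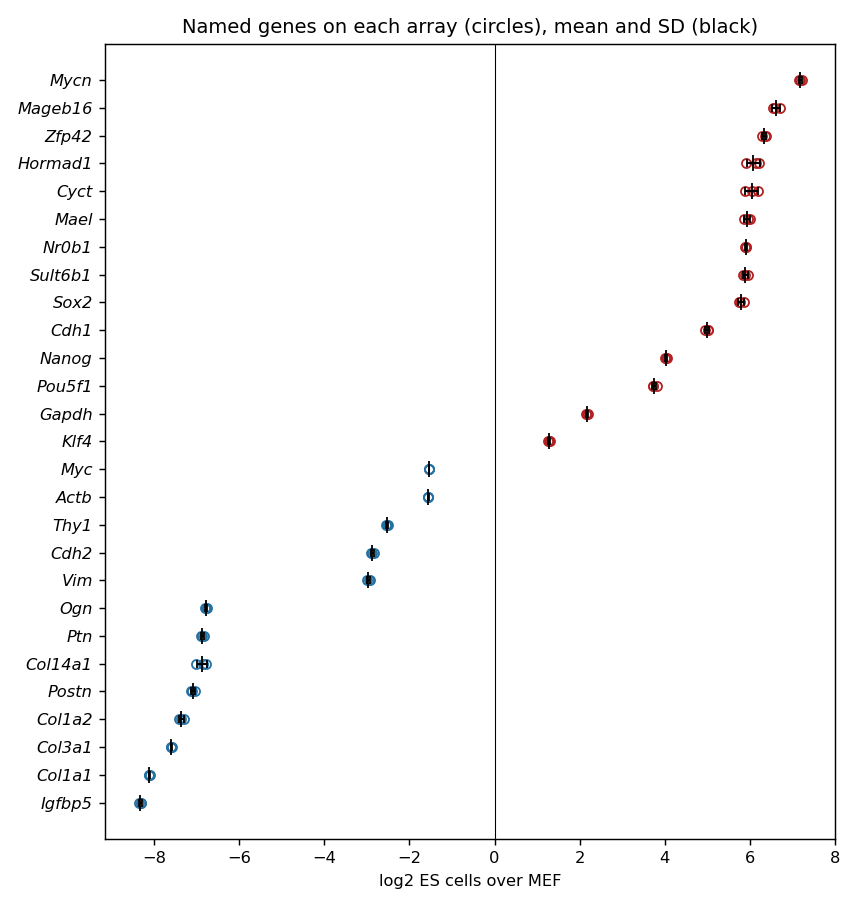
Log2 ratio of ES cells over MEF on each of the 3 arrays (circles), with the mean and SD (black), for the 8 highest and 8 lowest genes and the genes named in advance. The values span the range from Igfbp5 at -8.32 to Mycn at 7.18.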

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

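Signal appeared in control spots that no comparison uses. Apart from corner marks, 11 of the control probe designs were well above background in both channels on every spot. They stood out among 90 control designs. Among the 11, 9 share a name prefix that no source here explains; their names were not translated into genes. Median signals of the 11 designs ran from 222 to 179032 in the ES cell channel and from 172 to 501396 in the MEF channel. None of the 10 spike-in designs was above background on every spot, and their highest median signal was 132 in the ES cell channel and 137 in the MEF channel.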

How the results depend on the processing

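Removal of the trend on probe GC content was chosen after the data were seen, the other alternatives before. Between 3354 and 5124 genes were called higher and between 3761 and 4689 lower under the alternatives that kept 1 value per gene and the fold minimum. Without a fold minimum 8949 genes were higher and 9653 lower, since by construction small ratios then count. Leaving out 1 array gave 3934 to 3994 genes higher and 4331 to 4392 lower, 10 lists higher and 14 lower, and no chromosome. Median centring moved the median of all genes from -0.05 to 0.11 and the share of higher genes among those called from 47.6% to 56.3%. Processed signals (5108 higher, 4675 lower) and the authors' value table (5124 and 4683) also called more genes higher than lower. With an estimated correlation 0 lists were called higher and 0 lower, against 10 and 14 with the preset one. Contractile, fibroblast surface, primed epiblast and one-carbon genes had estimated correlations of -0.020, -0.018, -0.093 and -0.025, below the preset one. Their unadjusted camera p still rose, for contractile genes from 5.44e-07 to 0.0319. That argues against a stronger correlation as the cause for these lists. The estimated form takes its degrees of freedom from the 3 arrays, which raises p at any given correlation. The other called lists had estimates above the preset one, and for them the 2 effects were not separated. Median centring called 12 lists higher and 18 lower. The lists gained were DNA methylation and glycolysis genes, called higher, and G1 cyclin, Wnt, adipocyte and chondrocyte genes, called lower. Of the 24 lists called, 22 kept their call and direction under every other alternative run on lists, the exceptions being primed epiblast and neural genes. Every probe on its own, treat and no fold minimum were not run on lists or chromosomes. Chromosomes had 0 calls under every alternative run on them. Of 137 named genes, 136 kept the sign of their ratio. Hnf4a turned to -0.25 with processed signals, -0.19 without background subtraction, -0.23 with offset 0, and -0.18 with Aquantile or with a filter on both channels, where a probe other than the brightest came to stand for it. A ratio moved by over 1.5 times for 51 named genes: 32 with the mean of all probes, 27 with processed signals, 25 with the authors' value table, 18 with offset 0, and none without any 1 array. Signal over background limits the rest: genes not above background in one channel have only a bound. Slide and scan as a block were not run, since all arrays share them. Each ratio already pairs the ES cell and MEF channels of its array. No further pairing was possible because MEF is a single control on every array. The 3 arrays have 4 orientations in all, too few for a share under 0.05: the labelled one called 8345 genes (1 orientation with as many) and the highest of the others 0.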

Other observations

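The bootstrap intervals were added after the medians of the cell type lists were seen, and the pattern of Gfap and Aqp4 was then reworded; the lists and the limit of -1 for their medians were written before their values were seen but after the macrophage and Gfap ratios were known. In a list of 18 neuron genes, 13 of them tested and 1 also among the 37 lists, none was called lower in ES cells and 5 were called higher: the neurofilament gene Nefl at a log2 ratio of 4.51 ± 0.14 (SD, n = 3 arrays), the microtubule regulator gene Stmn2 at 4.35 ± 0.035, Elavl3 at 2.44 ± 0.017, Stmn3 at 1.73 ± 0.079, and Gad1, of GABA synthesis, at least 13.6-fold higher. In a list of 18 T and B cell genes, 11 of them tested, 3 were called higher in ES cells: the kinase genes Lck at 2.36 ± 0.030 and Zap70 at 2.31 ± 0.021, and Cd79b at 2.97 ± 0.087. The 1 called lower was Il7r at -1.01 ± 0.024, above background in ES cells on 1 of 3 arrays.

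The low ratios of macrophage and leukocyte genes raise the question whether the MEF culture held macrophages. A second list of 29 macrophage genes, none of them in the 37 lists, had a median log2 ratio of -3.81 (95% bootstrap interval -4.12 to -3.40), with 26 called lower in ES cells, 1 higher, all 29 above background in MEF on every array and 24 in ES cells; examples with their signal in MEF were C1qc (-5.47 ± 0.016, log2 signal 16.28), Mpeg1 (-4.83 ± 0.034, 15.03) and Trem2 (-4.88 ± 0.029, 14.94). The T and B cell list had a median of -0.012 (-0.23 to 0.15), but 10 of its 18 members had signal in ES cells too. Its members without signal in ES cells on any array (Blk, Cd28, Cd3g, Cd8a and Pax5) were not above background in MEF on all 3 arrays. That argues against a large share of lymphocytes. Random lists matched on brightness and probe GC content were drawn to test a dye bias that follows either. Of 10000 such lists 0% had a median as low as -4.97, the lowest being -1.93. Loess had removed the trend on brightness beforehand, so the draw could not test that part. For GC content, the median log2 ratio ran only from 0.31 up to 30% to -0.48 above 60%. That small range argues against a bias on GC content as the cause. Macrophages in the MEF culture are thus a candidate explanation, while expression of these genes by the fibroblasts themselves and dye bias of single probes were not tested and stay open.

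Gfap and Aqp4, both abundant in astrocytes, were also lower in ES cells than in MEF, with Gfap at least 37.8-fold lower by its brightest probe and smaller ratios at its other probes, none of them above background in ES cells, and Aqp4 at -2.68 ± 0.041 on its probe above background in both channels on all 3 arrays. For brain tissue with neurons in the MEF culture, the neuron list had a median of 0.40 (95% bootstrap interval -0.13 to 1.28), above the limit of -1. However, 13 of its 18 members had signal in ES cells too, such as Stmn2 (log2 signal 13.52) and Syn1 (12.94), so the median cannot exclude neurons. Members without signal in ES cells on any array (Dcx, Gad2, Sncb and Syt1) were not above background in MEF on all 3 arrays. That argues against a large share of neurons. Astrocytes may have been present: a list of 18 astrocyte genes without Gfap and Aqp4, 17 of them tested, had 7 called lower in ES cells, 1 higher and 9 not called, the lower ones including Fabp7 at -5.78 ± 0.083, Mlc1 at -3.85 ± 0.078 and Kcnj10 at -2.42 ± 0.028. Its median of -0.42 was above the limit of -1 and by itself would argue against astrocytes, but the interval added later, -1.59 to 0.0026, includes that limit, so the question stays open. The log2 signal in MEF was 13.45 for Fabp7, while Ptprz1 (18.44) and Aldh1l1 (11.94) were not called and had about as much signal in ES cells (18.14 and 12.13), so their ratios leave a small share of astrocytes open. Of 14 neural and neural crest genes, Gfap included, 9 were lower in ES cells, 1 was higher and 4 were not called. Other glia and neural crest cells were not tested as a source and stay open.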
